A study of Mus musculus with 6 samples.

How the data were processed

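Lungs of female C57BL/6J mice, wild type or lacking the chemokine receptor CCR5 (CCR5-/-), were profiled after tail vein injection of 100000 B16-F10 cells, a mouse melanoma line that seeds the lung. Per the labels' protocols, lungs were perfused with saline and frozen at 6, 24 or 48 h, and RNA of the 4 to 5 mice of a group was pooled by weight. Biotin-labelled cRNA of each pool went on 1 Affymetrix array, so the 6 groups have 1 array each. Spread between mice is lost in the pools. Uninjected lungs are not analysed here. Both 48 h samples carry a 24 h source name, while their titles and time point entries say 48 h, and the titles were followed.

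The deposited values are linear probe set intensities, 1 per probe set and array. The submitters' processing notes name MAS5, RMA and Affymetrix Expression Console without version, role or order, so which algorithm gave the values stays unknown. The genome build and annotation behind them are not given in the sources used here. Of 45101 probe sets, 64 were controls, 34945 had 1 gene symbol in the annotation table, 932 had several and 9160 had none there. Only probe sets with 1 symbol were named, and no symbol changed when updated by gene number.

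From the deposited intensities, each array was scaled to the same trimmed mean (2% off each end) and taken as log2(value + 16). Fold changes on this scale understate the change of dim genes. A gene was represented by its probe set with the highest mean, giving 18193 genes. Genes whose mean fell under the 40th percentile of probe sets (log2 7.46) were left out, which left 13354.

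Tests used limma 3.58.1 in R 4.3.3, with an additive model of genotype and time point over all 6 arrays, moderated by eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model has 2 residual degrees of freedom (prior 4.98), and its error is how far the genotype difference varies between time points plus array noise. A gene whose genotype difference changes with time therefore has a large error. The number of arrays limits the precision of every value. Genotype differences at a single time point rest on 1 array against 1 and have no test. They were described by size (at least 1 on the log2 scale) and, for gene lists, by the percentile of the list median among 10000 random lists of the same size matched on expression.

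Of 50 gene lists written before the data were examined, 48 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were the alternatives. List members were matched by current symbol, and by synonym only where a name is no current symbol. That second condition was added after results had been seen, because some names had been matched to another gene. Before it, the platelet list passed the genotype test and the ribosomal protein list did not. Lists of mucous genes, pigment genes, clock output genes, clock genes of opposite phase, T and B cell genes and monocyte markers without Ccr2 were added after the data were seen.

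The test was checked on simulated data, with 13354 genes of which 200 changed. For genotype it called 86.1% of genes changed by 0.5 on the log2 scale and 99.3% of those changed by 1. For 24 h against 6 h it called 62.4% and 98.8%. In the simulation, noise was alike on all arrays, genotype changes were the same at all times, and 200 changed genes eased the adjustment. These shares may be too high here: Bpifa1, at -0.50 for genotype (SE 0.08), had an adjusted p = 0.62. For lists of 15 independent genes shifted by 0.1, camera with the preset correlation called 98% for genotype and 88% for 24 h against 6 h, while the estimated correlation called 0% in both. For 24 h against 6 h the estimated correlation called 0% of lists shifted by 0.5 and 15% of those shifted by 0.75, and the median over simulations of the lowest adjusted p was 0.0923 and 0.0648. The preset value assumes nearly independent genes, so lists whose members move together are called too readily.

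Genes were named by a rule fixed before the data were examined: the largest changes past the test in each direction (12 for genotype, 8 for each step in time), filled with genes changed at least 1.5-fold the same way in every pair; the 5 largest per direction at single time points and in the genotypes' difference of time change; up to 4 members of a described list; chemokine genes tied to CCR5; and neighbours of Ccr5 among up to 25 nearest measured genes on each side, of which one side held 25 and the other 2. Neighbours were taken from RefSeq gene order (GRCm38.p6), without coordinates. Alternatives covered normalization, filter, probe set choice, pseudocount, variance prior, covariates and leaving out each array.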

Results

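Gene expression in whole lung was measured on 6 arrays, 1 for each combination of genotype (wild type, CCR5-/-) and time after melanoma cell injection (6, 24 and 48 h). Each array held pooled RNA of 4 to 5 mice, and no group had a second array. Median intensities lay between 217.2 and 220.8 on 5 arrays and at 234.3 on the CCR5-/- 48 h array. Bacterial control probe sets, which mark background, had medians of 30.3 to 32.7. The ratio of 5' to 3' signal for Gapdh, a sign of RNA or labelling quality, was 0.62 on the wild-type 48 h array and 0.75 to 0.87 on the others. Correlations of log2 values between arrays ranged from 0.97 to 0.996. Ccr5 itself is not analysed here, because no probe set carries its name alone in the annotation used. The genotype labels were therefore not checked against the targeted gene.

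The first comparison asked which lung genes differ when CCR5, a receptor for inflammatory chemokines, is missing. Clca1, a protein secreted by mucous cells of the airway, was higher in CCR5-/- lungs by 1.33 on the log2 scale (SE 0.085, adjusted p = 0.0036). Clec3b, which encodes tetranectin, a plasminogen-binding protein, was higher by 1.16 (SE 0.07, adjusted p = 0.0031). Mid1, a ubiquitin ligase gene at the pseudoautosomal boundary of the mouse X chromosome, had a difference of -2.04 (SE 0.105, adjusted p = 0.0022). Erdr1 had a difference of -1.59 (SE 0.085, adjusted p = 0.0022) and Limd1, a LIM domain adaptor, of -0.78 (SE 0.07, adjusted p = 0.030). These 5 genes, 2 higher and 3 lower, were those past limma's test among 13354. They were also the 5 genes with a difference of at least 1.5-fold and the same sign at all 3 time points. Exchanging the genotypes at 6, 24 or 48 h left 0, 1 and 0 such genes. At an unadjusted threshold of 0.05, 668 genes passed, close to the number that chance alone gives. This count depended on the arrays used: it was 1250 without the 48 h arrays, 650 without either 24 h array and 448 without either 6 h array. Leaving out either 48 h array, which in this model is the same genotype test as leaving out both, gave 15 genes, among them the clock genes Per1, Per2 and Hlf, picked out here after their values were seen.

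**Figure D1:**
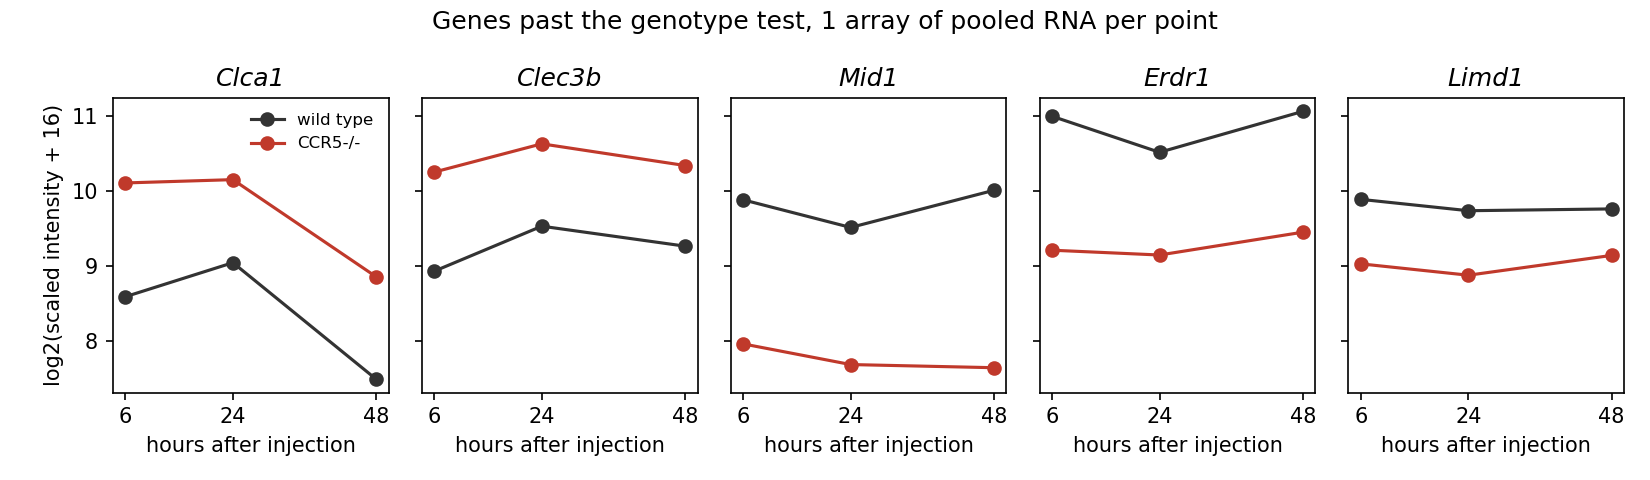
Log2(scaled intensity + 16) against hours after injection for the 5 genes past the genotype test, with wild-type arrays in black and CCR5-/- arrays in red, 1 array of pooled RNA per point. The lines do not cross: Mid1 differs by -1.92, -1.83 and -2.36 at 6, 24 and 48 h.

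Several of these calls rest on 1 probe set. The other Erdr1 probe set differed by -0.18. The other Mid1 probe sets, at low signal, differed by -0.10 and 0.11. The called Erdr1 probe set is of a type that can bind several transcripts, and Erdr1 did not pass with only probe sets without a suffix (adjusted p = 0.83). The other Clca1 probe set, near background, differed by 0.10. A second Limd1 probe set differed by -0.33 (SD 0.296 over the 3 pairs). Limd1 was the call lost without either 6 h array (adjusted p = 0.13), without either 24 h array (adjusted p = 0.066) and with no scaling and no pseudocount (adjusted p = 0.054). With the mean of all probe sets per gene only Clec3b passed, and Clca1 was at 0.71 (adjusted p = 0.053). Clec3b had no other probe set here, so averaging left its values unchanged and was no check on it. Mid1 lay under the filter in that setting and was not tested there.

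Clec3b and Limd1 lie near Ccr5, 11 and 7 measured genes away. Of 27 measured neighbours, 25 on one side and 2 on the other, 7 had an unadjusted p under 0.05, and these 2 passed after adjustment. Ccr2, the neighbouring receptor for Ccl2, gave different values by probe set. Its brightest probe set differed by -0.02 (SE 0.061, adjusted p = 0.96). A second one read 1360, 622 and 744 in wild-type lungs and 576, 452 and 391 in CCR5-/- lungs at 6, 24 and 48 h. Another read 849, 449 and 288 against 277, 166 and 218.

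**Figure D2:**
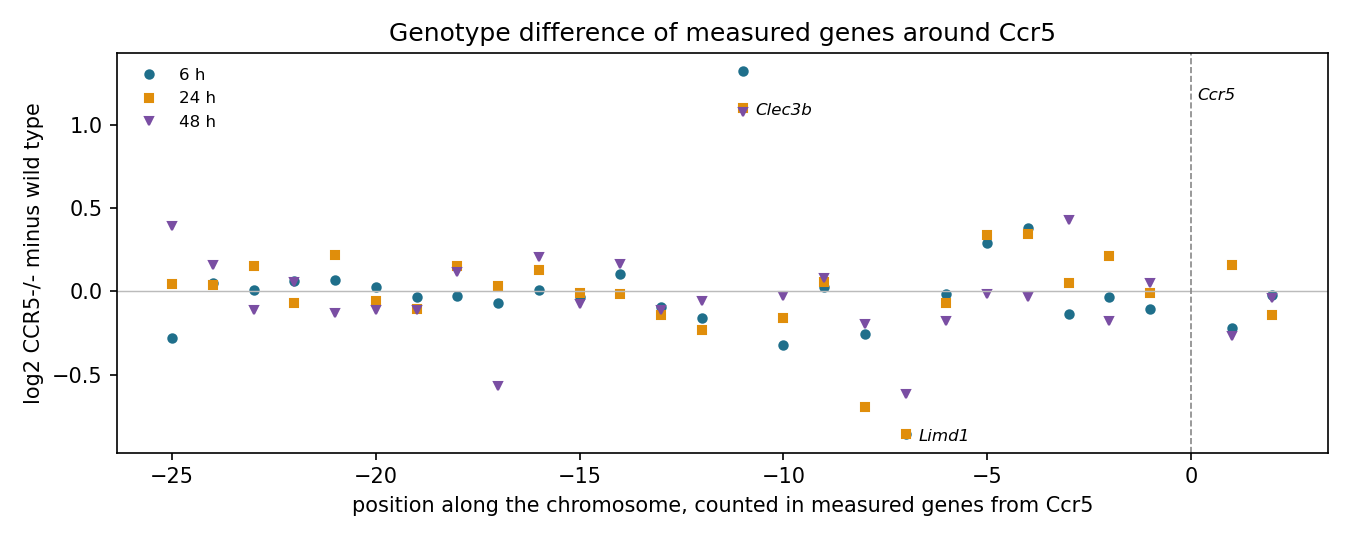
Difference between CCR5-/- and wild-type arrays (log2) for measured genes around Ccr5, placed by gene order, with 1 symbol per time point. Clec3b lies at 1.07 to 1.32 and Limd1 at -0.86 to -0.62, while Lars2, which did not pass the test, spans -0.70 to -0.20.

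Among chemokines, no genotype difference passed the test. Ccl2, the main monocyte attractant, differed by -0.13, -0.18 and -0.02 at the 3 times, and Mmp9, a gelatinase, by -0.16, -0.05 and -0.20. A second, dimmer Mmp9 probe set differed by -0.55, -0.37 and -0.14. The CCR5 ligands Ccl4 (0.04, 0.08 and 0.08) and Ccl5 (-0.07, 0.24 and 0.03) are of like size, and Ccl3 was too dim to test.

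Of type I interferon genes, 19 of 21 had a positive difference in CCR5-/- lungs (mean 0.09), with Ifit3 at 0.24 and Rsad2 at 0.19. The list passed with camera's preset correlation (adjusted p = 0.00023) and not with an estimated correlation (adjusted p = 0.54). Of immediate early genes, 17 of 21 had a negative difference (mean -0.14), with Fos at -0.52 and Egr1 at -0.44 (camera adjusted p = 3.92e-05, or adjusted p = 0.54 with an estimated correlation). Of MHC class II genes, used to present antigen, 9 of 9 did (mean -0.12), with Ciita at -0.31 and H2-Ab1 at -0.18 (camera adjusted p = 0.00046, or adjusted p = 0.54 with an estimated correlation). No member of these 3 lists passed on its own over all genes. Adjusted over the list alone, 0 interferon, 4 immediate early and 0 MHC class II genes did. In all, 15 of 48 lists passed, 2 higher and 13 lower, and these 3 passed in all 18 other fits with camera's preset correlation, of which 14 are distinct for genotype. With an estimated correlation 0 lists passed, and fry called 0. Ribosomal proteins (adjusted p = 0.046) and platelet genes (adjusted p = 0.075) lay on either side of the threshold. Without either 6 h array 7 lists passed.

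At single time points each value sets 1 array against 1, and differences between time points were not tested. Neutrophil genes had a median difference of -0.48 at 6 h, -0.04 at 24 h and 0.03 at 48 h, and 16 of 16 members were lower at 6 h. Beside them at 6 h, red cell genes had a median of -0.27, platelet genes -0.27 and adipocyte genes -0.40, with Adipoq at -1.52. Adipocyte genes were at -0.14 at 24 h and 0.10 at 48 h. Skeletal muscle genes varied between arrays without a shared sign (0.17, -0.38 and 0.25). Circadian clock genes had medians of 0.22, 0.18 and -0.05, with Dbp at 1.11, 0.44 and -0.38. Over all time points the clock list passed as higher in CCR5-/- lungs (camera adjusted p = 0.017, or adjusted p = 0.54 with an estimated correlation). That call was lost without any 1 of the 6 h or 24 h arrays. Genes with at least a 2-fold difference numbered 17 at 6 h, 7 at 24 h and 12 at 48 h. Besides the 5 genes above, Adipoq and Dbp, the largest at 6 h were Pdk4 (-1.46), the neutrophil gene S100a9 (-1.32), Lrat (1.02) and the acute phase gene Saa3 (1.01). At 24 h they were the keratin gene Krt4 (-2.23), the muscle actin gene Acta1 (-1.51), Cyp26b1 (-1.14), Itga9 (0.79) and the heat shock genes Hspa1a and Hspa1b (0.99 and 0.76). At 48 h they were Slc6a14 (-1.43), Meis2 (-1.23), Slc29a3 (-1.16), Cyp1a1 (1.72), a detoxifying oxidase, Cyp26b1 (1.08) and the cytokine Il1b (0.80). Several of these values rest on 1 probe set. Other probe sets gave 0.40 for Slc6a14, -0.18, -0.21 and -0.04 for Meis2 and -0.10 for Slc29a3 at 48 h, and 0.06 and 0.12 for Itga9 at 24 h. None of these genes passed the test over all time points. Across genes, which are not independent replicates, genotype differences had Pearson correlations of 0.22 between 6 and 24 h, 0.06 between 6 and 48 h and -0.004 between 24 and 48 h.

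The second comparison followed both genotypes from 6 to 24 h. Metallothioneins, which bind metal ions, changed most: Mt2 fell by 2.94 (SE 0.091, adjusted p = 9.36e-05) and Mt1 fell by 2.32 (SE 0.118, adjusted p = 0.00072). The other leading falls were the chemokine Ccl17 (-2.15), the cholesterol hydroxylase Ch25h (-1.78), Gm13889 (-1.75), the glucocorticoid target Fkbp5 (-1.62), the monocyte transglutaminase F13a1 (-1.53) and the thrombospondin gene Thbs1 (-1.53). Genes that rose included Stmn2 (1.44), Tubb2b (1.13), the matrix gene Hmcn1 (1.13), Pdgfd (1.12), Aard (1.09), the chemokine Cxcl12 (0.98), Ushbp1 (0.95) and Tmeff1 (0.94). Cxcl12 did not pass without wild-type 6 h (adjusted p = 0.069) or wild-type 24 h (adjusted p = 0.064). In total 519 genes passed, 288 higher and 231 lower, and of 36 changed at least 2-fold 31 were lower. Time changes in wild-type and CCR5-/- lungs correlated at 0.75 across genes. The hour of collection is not known here, so changes with hour of day and changes after injection cannot be told apart. Of clock genes, Nr1d1 rose by 0.57 (limma adjusted p = 0.021), while the circadian clock list did not pass (camera adjusted p = 0.37). Median centring of the arrays gave 455 higher and 212 lower. More genes were lower than higher without any 1 of the 6 h or 24 h arrays: 80 higher and 121 lower (201) without CCR5-/- 6 h, 55 and 84 (139) without CCR5-/- 24 h, 20 and 59 (79) without wild-type 6 h, and 36 and 77 (113) without wild-type 24 h. Without either 48 h array 2427 genes passed, 1444 higher and 983 lower.

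From 6 to 24 h, of 10 tested genes of Ly6C monocytes, the inflammatory blood monocytes, 8 fell, or 10 adjusted over the list alone, and Ms4a6c was at -0.91 and Vcan at -0.84 (camera adjusted p = 3.00e-12, but adjusted p = 0.33 with an estimated correlation). Among glucocorticoid response genes 9 of 19 fell (12 over the list alone), with Mt2 and Mt1 above and Angptl4 at -1.35 (adjusted p = 3.00e-12, or adjusted p = 0.33 with an estimated correlation). NF-kB and cytokine genes fell in 7 of 19 (14 over the list alone), including Bcl3 (-0.93) and Tnfaip3 (-0.55), with a camera adjusted p = 1.24e-11. Acute phase genes fell in 4 of 12 (7 over the list alone, adjusted p = 2.99e-06), including Socs3 (-1.48) and Cebpd (-1.08). Among CC chemokines 5 of 13 fell (6 over the list alone, adjusted p = 0.00028), among them Ccl22 (-0.92), Ccl9 (-0.87) and Ccl2 (-0.66, adjusted p = 0.0086). These 3 lists also had an adjusted p = 0.33 with an estimated correlation. Fry called 6 lists: Ly6C monocyte, NF-kB, CC chemokine and melanocyte genes lower, and proliferation and matrix genes higher.

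Genes of other groups rose from 6 to 24 h. Endothelial genes rose in 6 of 20 (11 higher and 1 lower over the list alone, camera adjusted p = 0.000998), including Aplnr (0.74) and the angiopoietin receptor Tek (0.67). Matrix genes rose in 4 of 19 and 1 fell (7 higher and 3 lower over the list alone, adjusted p = 0.021), with Col1a1 at 0.54 and Col1a2 at 0.47 against Lox at -0.75. The matrix list lost its camera call with the 60th percentile filter, without wild-type 6 h and without wild-type 24 h (highest adjusted p = 0.068). Complement genes rose in 2 of 12 (6 higher and 1 lower over the list alone, adjusted p = 0.0049), C1qc by 0.57 and C1qa by 0.56. With an estimated correlation the adjusted p was 0.45, 0.43 and 0.43 for these lists.

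**Figure D3:**
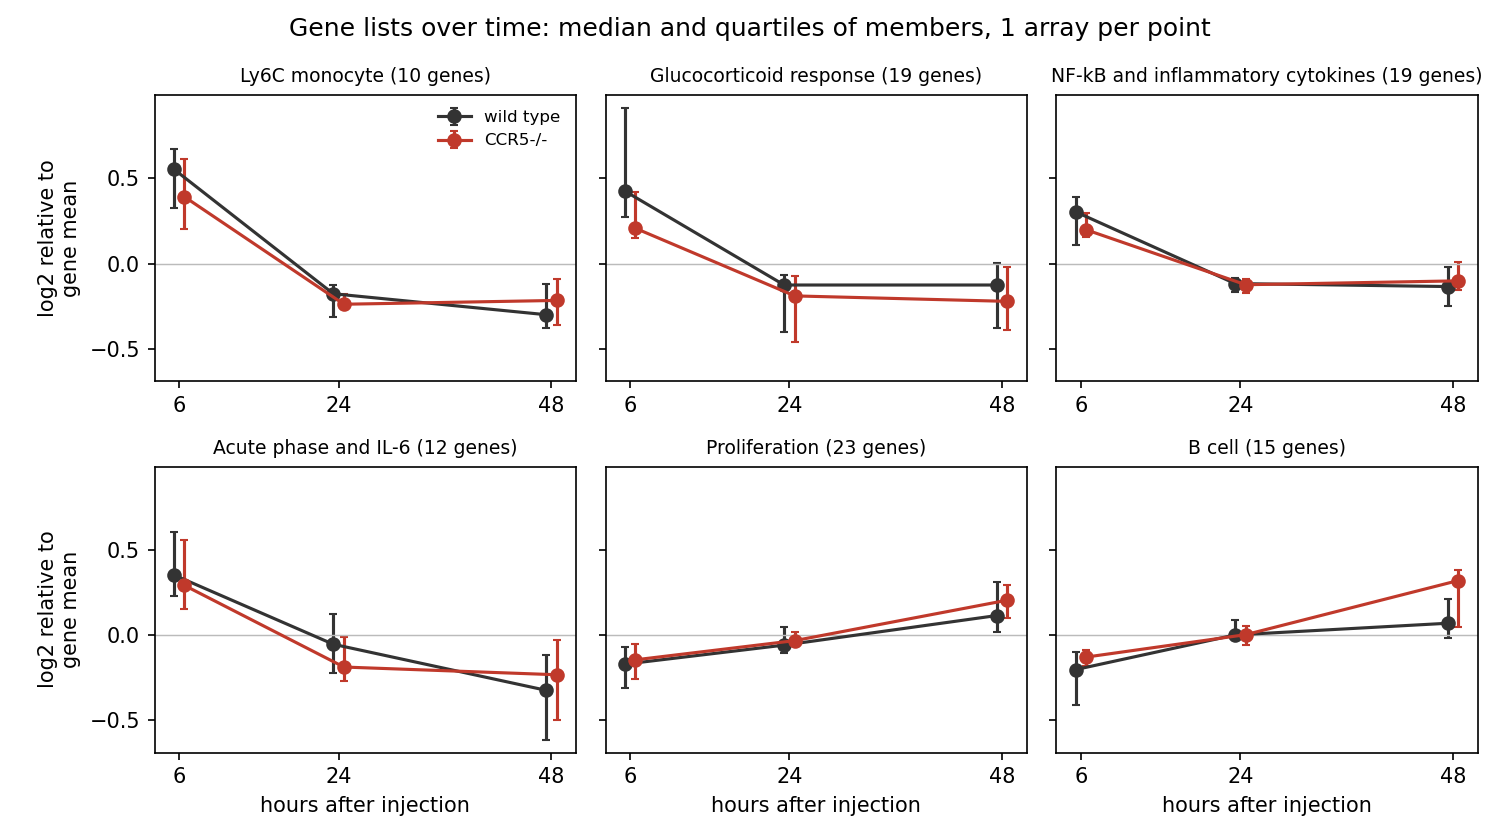
Median and quartiles of list members (log2 relative to each gene's mean over the 6 arrays) against hours after injection, wild type in black and CCR5-/- in red, 1 array per point. The Ly6C monocyte median goes from 0.55 at 6 h to -0.18 at 24 h in wild-type lungs, and the proliferation median from -0.17 at 6 h to 0.12 at 48 h.

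Pigment cell genes, which the injected melanoma cells express, also fell from 6 to 24 h. Pmel fell by 1.13 (SE 0.076, adjusted p = 0.0018), Dct by 1.07, Tyrp1 by 0.79 and Mlana by 0.66. These 4 of 17 tested members of the melanocyte list passed (6 over the list alone), and the list passed with camera (adjusted p = 3.12e-06) and fry (adjusted p = 0.0073), but not with an estimated correlation (adjusted p = 0.33). From 24 to 48 h none of the 4 passed. The 3 Tyrp1 probe sets were lower in CCR5-/- lungs at all 3 times, with mean differences of -0.70, -0.28 and -0.32. The last of these stood for the gene and did not pass limma's genotype test (adjusted p = 0.85). The others were not tested. The 4 genes together, a list made after their values were seen, had median genotype differences of -0.33, -0.27 and -0.12 at 6, 24 and 48 h. Over the 17 genes of the melanocyte list the medians were 0.0036, 0.0099 and -0.073, with 7 of 17 mean differences positive (camera adjusted p = 0.046, lower, or adjusted p = 0.54 with an estimated correlation). That call held in 9 of 18 other fits and was lost in the rest, among them those without any 1 of the 6 h or 24 h arrays (highest adjusted p = 0.42).

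**Figure D4:**
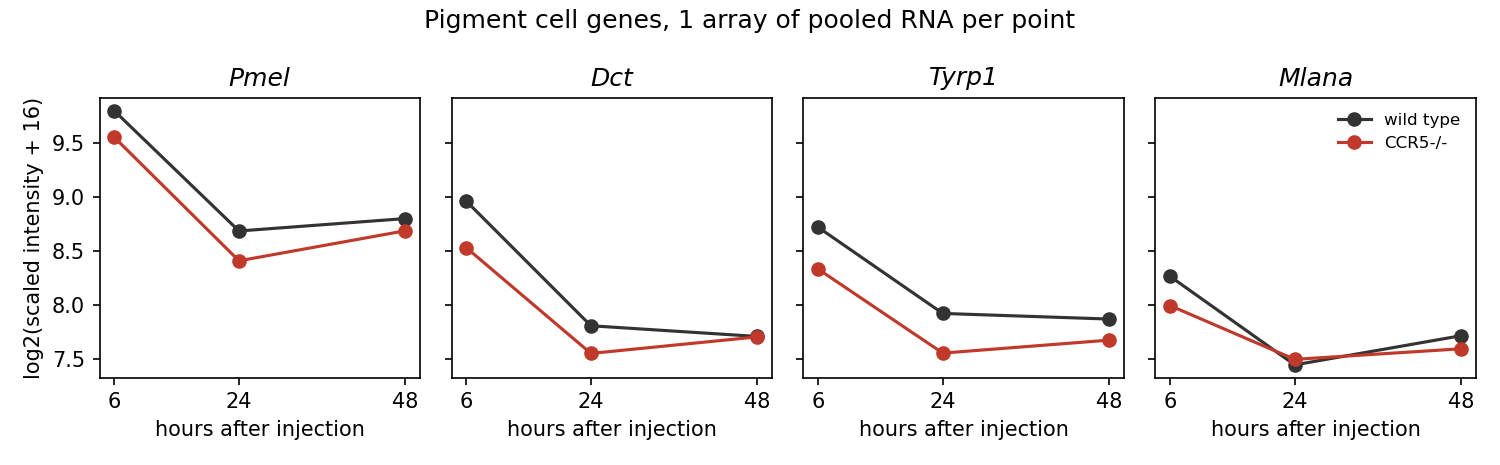
Log2(scaled intensity + 16) of 4 pigment cell genes against hours after injection, wild type in black and CCR5-/- in red, 1 array of pooled RNA per point. Pmel goes from 9.79 to 8.68 between 6 and 24 h in wild-type lungs and from 9.55 to 8.41 in CCR5-/- lungs.

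From 24 to 48 h few genes passed. Clca1 fell by 1.42 (SE 0.104), the interferon-induced chemokine Cxcl10 by 1.21 (SE 0.079) and the acute phase gene Serpina3n by 1.08 (SE 0.077), each with an adjusted p = 0.012, and 0 genes passed as higher. The Clca1 call was lost with the mean of probe sets (-0.68, adjusted p = 0.12) and without the genotype in the model (adjusted p = 0.39). At an unadjusted p under 0.05 there were 1762 genes, 1003 higher and 759 lower. Saa3, an acute phase protein, was at -2.41 and Timp1, a protease inhibitor, at -1.48, with the same sign in both genotypes, and neither passed (adjusted p = 0.19 and 0.082). Max (-0.90), Ggcx (-0.81), Zbtb16 (1.06) and Bex1 (0.68) also moved at least 1.5-fold in both genotypes without passing. Leaving out a 48 h array leaves 1 array at 48 h, so the calls then depend on how far that array departs from the rest. The wild-type 48 h array had the low 5' to 3' ratio, and the CCR5-/- 48 h array the higher median (234.3 against 218.2). The CCR5-/- 48 h array correlated at 0.987 with the CCR5-/- 24 h array, against 0.991 between the wild-type arrays of these times. The count of genes past the test also changed in other fits. It was 7 without either 6 h array and 8 without CCR5-/- 24 h, with Zbtb16 the 1 gene higher in each of these fits. Time changes of the 2 genotypes correlated at 0.22 across genes.

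In this step 7 of 48 lists passed. Each had an adjusted p = 0.77 with an estimated correlation, and 0 members of the 3 lists named here passed over all genes. Of type I interferon genes, 17 of 21 were negative (7 lower over the list alone, camera adjusted p = 1.10e-05), with Ifit3 at -0.57 and Ifit1 at -0.53. Of heat shock genes, 13 of 15 were negative (0 over the list alone, adjusted p = 0.0021), with Hsp90aa1 at -0.37. Of proliferation genes, 20 of 23 were positive (10 higher and 1 lower over the list alone, adjusted p = 1.10e-05), with Cdc20 at 0.88 and Mki67 at 0.59. Fry called the proliferation list alone.

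Over the whole course from 6 to 48 h, 1220 genes passed, 703 higher and 517 lower, or 992 higher and 386 lower with no scaling and no pseudocount. Cell cycle genes rose in 12 of 23 (17 over the list alone, camera adjusted p = 1.76e-08), with Mki67 at 1.21 and Top2a at 0.96, and B cell genes in 6 of 15 (11 over the list alone, adjusted p = 1.74e-05), with Cd79b at 0.62 and Cd79a at 0.59. The adjusted p with an estimated correlation was 0.34 and 0.46. Time changes of the 2 genotypes correlated at 0.59. More genes were lower than higher without either 6 h array, with 156 higher and 187 lower (343) without CCR5-/- 6 h and 90 and 141 (231) without wild-type 6 h. The count was 2774 without CCR5-/- 48 h and 3589 without wild-type 48 h.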

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

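The test of residual blood below was chosen after the result was seen. Some genes moved in opposite directions in the genotypes, and with 1 array per point the difference was not tested. From 6 to 24 h, CCR5-/- minus wild-type changes were -2.38 for Acta1, -2.28 for Krt4, -1.78 for Saa3 and -1.6 for Cyp26b1. They were 1.64 for Alas2, 1.4 for Hbb-b2, 1.39 for Adipoq and 1.32 for Ngp. From 24 to 48 h they were -1.69 for Ngp, -1.26 for Meis2, -1.24 for Zfp800, -1.21 for 4933417O13Rik, 2.46 for Krt4, 2.22 for Cyp26b1 and 1.26 for Lce3f. Some of these rest on 1 probe set of the gene: at 48 h the others differed between genotypes by -0.21 to -0.04 for Meis2 and by -0.31 to 0.30 for Zfp800, and at 6 h the other Hbb-b2 probe set differed by 0.03. Krt4, an epithelial keratin, and Acta1, a skeletal muscle actin, were highest on the wild-type 24 h array among the wild-type arrays.

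Less blood left in the CCR5-/- lungs at 6 h may account for the lower neutrophil list there. T and B cell genes, the first choice for its test, had a median difference of 0.03 at 6 h, which goes against it, though lung tissue holds such cells of its own. Red cell genes, which took their place after that value was seen, had a median of -0.274 (SD 0.456 over 6 genes). The SD is the spread between genes on the same arrays and gives no error for the genotype difference. The globin genes of that list, Hba-a1, Hbb-b1 and Hbb-bt, were not among the 6 tested. Without Alas2, which is among the genes listed above, the red cell median was -0.20. Platelet genes had a median of -0.27 at 6 h, with 11 of 11 lower. These values do not decide for or against less blood. A difference in neutrophil entry by genotype stays open and untested.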

How the results depend on the processing

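Of the genes named for genotype over all time points and for the 24 h and 48 h steps, none changed direction under an alternative that gave a value. In all, 482 values kept their side of the threshold, 16 lost the call and 25 gained one. A gene under the filter of a setting has no value there. These genes were named for passing the test or for a shared sign in every pair. Their kept direction when an array is left out was therefore largely fixed by that choice. The genotype test already pairs the arrays of a time point. Causes were not tested except where stated. The settings "no scaling and no pseudocount" and "without both 48 h arrays" were chosen after seeing the data. With the mean of probe sets, genotype gave 1 gene, 24 to 48 h 4 lists, single time points 11, 4 and 6 genes at 6, 24 and 48 h, and 3 genes had a shared 1.5-fold difference. Without the time point in the model 2 genes, Mid1 and Erdr1, differed by genotype. With only probe sets without a suffix 11 genes differed 2-fold at 6 h, and with no filter 11 did at 24 h. With no scaling and no pseudocount 5 genes passed from 24 to 48 h. Without both 48 h arrays genotype gave 15 genes and 24 h against 6 h 2427. Camera with the correlation estimated for each list called 0 lists in all 4 comparisons (lowest adjusted p = 0.54 for genotype, 0.33 for 24 h against 6 h, 0.77 for 48 h against 24 h and 0.34 for 48 h against 6 h). On simulated lists of independent genes shifted by 0.75 it called 33%, 15% and 25% in the first 3 comparisons. Fry in place of camera called 0 lists for genotype, 6 for 24 h against 6 h, 1 for 48 h against 24 h and 5 for 48 h against 6 h. Leaving out 1 array at a time gave 4 to 15 genes for genotype, 79 to 2427 for 24 h against 6 h, 4 to 1886 for 48 h against 24 h and 231 to 3589 for 48 h against 6 h. Lists ranged from 7 to 20, 17 to 22, 7 to 13 and 17 to 24. Counts for a step in time from a fit that leaves 1 array at a compared time depend on how far that array departs from the rest. The genotype neutrophil shift turned positive without either 6 h array, the ribosomal one turned with only probe sets without a suffix, and the adipocyte falls in time turned without wild-type 6 h. The gene correlations moved by less than 0.1 in every setting that gave them. Signal over background limits dim genes such as Ccl3.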

Other observations

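The tests of the Ccr5 neighbours, Ccr2, clock and mucous genes in this part were chosen after the result was seen. In the endothelial activation list 5 of 12 genes fell from 6 to 24 h and 1 rose (8 lower and 2 higher over the list alone), including Plat (-0.98) and the tissue factor gene F3 (-0.64), while Thbd, named after its value was seen, rose by 0.41 (camera adjusted p = 0.00046, adjusted p = 0.33 with an estimated correlation). Hypoxia and glycolysis genes fell in 4 of 17 (4 over the list alone), with Adm at -1.27 and Hk2 at -0.51 (adjusted p = 0.0028, adjusted p = 0.45 with an estimated correlation).

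The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 5 genes and the highest other 442, with counts as large in 3 splits. Splits that part only the same pair are the same fit, so this count of splits and that for lists include repeats. The splits with 442 genes part only the 48 h pair. They set 1 array against 1, so what they fit is the genotype difference at 48 h. The spread is taken from the 6 and 24 h pairs. With 1 array per genotype at 48 h, genotype and array differences cannot be told apart. These splits are therefore no reference free of genotype. The 48 h arrays were further apart (SD of the difference over genes 0.202) than those at 6 h (0.128) and 24 h (0.11). The 3 other splits that part all 3 pairs, as the real one does, gave 0 genes each. For lists the real split gave 15 and the highest other 17, with counts as large in 5 splits. The splits with more lists than 15 part 1 pair only, so they too fit the genotype difference at a single time point. The 3 others that part all 3 pairs gave 14, 8 and 9 lists.

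Genes around Ccr5 may differ because DNA of the donor strain around the targeted locus was kept, which the labels do not address. Windows of 27 consecutive measured genes with at least 7 at an unadjusted p under 0.05 made up 0.0547% of 12804 overlapping windows, those at Ccr5 included. Without Clec3b and Limd1, 5 of 25 neighbours were still under 0.05. A strain variant under a probe set in place of a change of level cannot be told apart for Limd1, since its other probe set showed 0.429 of the called difference. An effect of losing CCR5 itself stays open and untested.

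The low Ccr2 probe sets were set against fewer Ly6C monocytes. The 9 other monocyte markers had a median of -0.234 at 6 h (SD 0.266), against a mean of -1.39 at 6 h for the 2 lowest Ccr2 probe sets. The remaining Ccr2 probe sets differed by -0.59 and -0.11 at 6 h. Because the 2 were picked as the lowest, from 1 array against 1, the gap does not decide for or against fewer monocytes. Probes shared with the deleted paralog stay open, since probe sequences are not used here, and 3 of the 4 Ccr2 probe sets were lower at all 3 times.

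Pools collected at another hour of the day could underlie the clock gene differences. Clock output genes such as Dbp and Per2 exceeded genes of opposite phase (Arntl, Clock and Cry1) in their genotype difference by 0.591 at 6 h and 0.38 at 24 h, and by -0.50 at 48 h. Without Cry1, a repressor that peaks late, the gaps were 0.73, 0.46 and -0.31. At 6 h all 10 output genes were higher and Arntl, Clock and Cry1 lower. Dbp and the clock list had been seen before this test, and an effect of genotype on the clock stays open.

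More mucous cells were considered as a hypothesis for the higher Clca1. The other 12 mucous genes had a median difference of 0.0524 (SD 0.237), under the bound of 0.1 set after the result was seen. The highest was Tff2 (0.24) and the lowest Ltf (-0.51), so none rose as far as Clca1. Muc5ac, Spdef and Chil4 were dim, with wild-type means of 8.0, 7.6 and 7.5. These values show no broad rise of mucous genes, but do not exclude a smaller one in mucous cells.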
